A study of Homo sapiens with 12 samples.

How the data were processed

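RNA of BeWo and JEG-3 cells was measured on Affymetrix gene arrays, 3 arrays in each of 4 groups: BeWo control, BeWo forskolin, JEG-3 control and JEG-3 forskolin. The labels' titles gave the group and replicate number of every array, and 0 sample columns in the table were left unmapped. Per the labels' protocols, cells were treated with forskolin for 48 h in different amounts, doubly positive cells were sorted, and total RNA was labelled with biotin by the methods the array maker recommends. The dose of each array is not given in the sources used here.

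The deposited values were read as log2 signal summaries of probe sets, since they ran from 1.58 to 14.2 over the 12 arrays with nearly equal medians. The quartiles of the 12 columns were close to each other but not identical. Whether and how the arrays were normalized to each other, the summary method and the genome build are not given in the sources used here, and no coordinates are printed. The table carries no detection calls and no scan dates, so no background filter or batch term was used, and signal over background is unknown.

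The table held 257430 probe sets at exon level, of which 224320 carried 1 gene symbol in the platform annotation, 10159 several and 22951 none. Only probe sets with 1 symbol named a gene. Of 18701 symbols, 16068 were current in the NCBI RefSeq gene table, 2574 were updated through a synonym, 55 ambiguous and 4 unmatched symbols were kept as given, and 18656 genes were tested. A gene had a median of 10 probe sets. The rule fixed before the data were examined took for each gene the probe set with the highest mean over the 12 arrays. It had been written for a table with about 1 value for each gene, and at exon level a single probe set can stand apart from the rest of its gene, so the mean of all probe sets, fixed at the same time as an alternative, is given beside a result wherever the call or size depended on it.

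Differential expression was tested with limma 3.58.1 (R 4.3.3) on the values as deposited, with lmFit, contrasts and eBayes in 1 model of the 4 group means over all 12 arrays, so that every comparison shared a single estimate of the spread. The comparisons were forskolin against control in each line, the difference of these effects, and BeWo against JEG-3 among control arrays and among forskolin arrays. P-values were adjusted by the Benjamini-Hochberg method over 18656 genes, and a gene was called at an adjusted p under 0.05. The prior degrees of freedom were 2.57. All tests are two-sided. Errors of log2 changes are standard errors and those of group means are standard deviations over 3 arrays. Values were read with the R package data.table (version 1.17.8) and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

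There were 29 gene lists, fixed before the data were examined, on trophoblast fusion, hormones, steroid and cholesterol synthesis, cyclic AMP targets, the cell cycle, trophoblast subtypes, junctions, cytoskeleton, apoptosis, stress responses, transport, signalling, imprinting, other cell types and reference genes. They were tested with camera at a preset correlation of 0.01, and 28 of them had at least 5 measured members. Mitochondrially encoded genes had 0 measured members and were not tested. Calls kept with an estimated correlation were 5 in BeWo (fusion, hormone, cyclic AMP, extravillous and metallothionein lists), 1 in JEG-3 (fusion) and 0 for the difference. Named in the text are the 10 largest rises and falls per forskolin comparison and for their difference, among called genes and, for the forskolin comparisons, those whose 3 treated arrays all lay beyond the 3 controls. Also named are the 5 largest each way between control lines, up to 2 rises and 2 falls among the called members of a list or, with none called, the member with the smallest p, and 16 genes fixed in advance, of which the last was whichever CGB gene was brightest. Y-linked genes, XIST, and genes named only by a locus or non-coding class were counted and not named.

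The model was checked on simulated data for the BeWo comparison with 200 of 18656 genes changed. At a log2 change of 0.5 it recovered 0% of them, at 1 it recovered 71.5% with 5 false calls, and at 2 it recovered 98.0% with 10 false calls. The list test, run on 28 lists, found each of 2 lists shifted by 0.5, with 0 and 1 other lists called. The simulated genes varied independently, whereas the estimated correlation within a list of the real data reached 0.44 (metallothioneins). False calls from correlated genes were therefore not tested, nor was recovery with more than 200 genes changed.

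Alternatives fixed in advance were quantile normalization, median centring, a filter on dim genes, the mean of all probe sets, each probe set singly, a trended and robust prior, array weights, 2-fold thresholds, fits on the 6 arrays compared, the replicate number as a block, an estimated list correlation, fry, and leaving out each array in turn. The median of all probe sets, the mean of the others with the brightest left out, a residual component as covariate, and lists over the mean or median of probe sets were added after seeing the data.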

Results

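RNA from 2 human choriocarcinoma cell lines, BeWo and JEG-3, was measured on 12 arrays with and without forskolin. Both lines serve as models of placental trophoblast, and forskolin activates adenylyl cyclase and raises cyclic AMP, a signal that drives trophoblast cells to fuse into multinucleated syncytia. Each line had 3 control arrays and 3 arrays of cells exposed to forskolin for 48 h. According to the labels, fusion was induced with forskolin and doubly positive cells were then collected by fluorescence-activated sorting before RNA extraction. The sources used here give neither a forskolin dose nor whether the control cells were sorted, so effects of the drug and of sorting cannot be told apart. The question posed by the design was how forskolin changed the transcriptome of each line. The array medians lay between 6.49 and 6.53 on the log2 scale, and replicate arrays correlated across probe sets with r from 0.955 to 0.979. The precision was limited by the number of arrays, 3 per group. Nothing states that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. The first principal component held 27.9% of the variance over genes and the second 23.1%.

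Among the genes that rose in forskolin-treated BeWo cells were genes of placental hormones and of cell fusion. INSL4, an insulin-like peptide of the placenta, rose 11.4-fold from 6.02±0.20 to 9.54±0.18 on the log2 scale (SD, n = 3 each), a change of 3.52±0.13 (SE, limma adjusted p = 2.13e-07; 2.20 over all probe sets). CGA, the alpha subunit shared by chorionic gonadotropin and the pituitary glycoprotein hormones, rose by 2.44±0.11 (adjusted p = 1.34e-06). The envelope gene of syncytin-2, ERVFRD-1, rose 4.62-fold (2.21±0.22, adjusted p = 2.02e-04) and that of syncytin-1, ERVW-1, 2.42-fold (1.27±0.16, adjusted p = 0.00129). GCM1, the transcription factor that drives syncytin expression, rose by 1.19±0.08 (adjusted p = 2.27e-05), and the epithelial transcriptional repressor OVOL1 by 1.98±0.10 (adjusted p = 2.56e-06). TP63 and TEAD4, transcription factors of proliferating cytotrophoblast, changed by -0.80±0.13 (adjusted p = 0.00617) and -0.61±0.09 (adjusted p = 0.00390).

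In BeWo, 385 of 18656 genes rose and 292 fell at an adjusted p under 0.05, and 128 of the rises and 50 of the falls were at least 2-fold. Each gene was read from its brightest probe set. Where the mean over all probe sets of a named gene ended or made the call, turned the direction or differed in size by over 1.5 times, that value follows in parentheses after the words all probe sets. The largest rise belonged to LAIR2 (4.80±0.14, all probe sets 2.56), a secreted immunoglobulin-like receptor of extravillous trophoblast. Next came EEIG2 (3.73±0.13), INSL4 (3.52±0.13, all probe sets 2.20), the trefoil peptide TFF1 (3.40±0.17), NLRP9 (2.98±0.19, all probe sets 0.78), CRISPLD1 (2.64±0.21), the adhesion molecule MCAM (2.49±0.23), the receptor kinase feedback inhibitor SPRY2 (2.46±0.54, all probe sets 1.11), CGA (2.44±0.11) and LYPD3 (2.43±0.16, all probe sets 1.42). The largest falls were those of the folate enzyme ALDH1L1 (-2.09±0.31, all probe sets -0.14, not called), the hyaluronan receptor LAYN (-2.01±0.20), the peptidase NAALAD2 (-2.0±0.15), the glycosyltransferase GCNT2 (-1.91±0.32, all probe sets -1.22) and ENC1 (-1.91±0.10). They were followed by SLC44A5 (-1.81±0.20, all probe sets -0.20, not called), the ephrin receptor EPHA4 (-1.81±0.21), LARGE2 (-1.76±0.17, all probe sets -1.02), ACP3 (-1.73±0.25, all probe sets -0.91) and CLCA2 (-1.67±0.36, all probe sets -0.76). With the mean of all probe sets 678 genes rose and 688 fell, and 516 genes were called in the same direction by both summaries. Without BeWo control replicate 3 the count was 450. It was 319 with the replicate number as a block and 304 in a fit of the 6 BeWo arrays alone.

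The fusion list of BeWo passed the list test upward. Of 24 genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 1.48e-06, and adjusted p = 0.00894 with an estimated correlation). So did the placental hormone list. Of 22 genes, 6 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 4.07e-10, and adjusted p = 0.0109 with an estimated correlation). PGF, placental growth factor, rose by 1.77±0.08 (adjusted p = 1.62e-06), and CGB5, the brightest of the singly annotated chorionic gonadotropin beta genes, stood at 0.50±0.17 (adjusted p = 0.174). Another 20 probe sets, shared by several CGB genes, are not used in the gene tests. Of these 15 rose and 0 fell in BeWo, with a median change of 2.81. Targets of cyclic AMP and CREB rose as well, led by NR4A1 (1.90±0.27, all probe sets 1.26), an orphan nuclear receptor, and DUSP1 (1.41±0.12), a phosphatase of MAP kinases. Of 23 genes, 9 rose and 0 fell (10 and 2 adjusted over the list alone, camera adjusted p = 9.08e-07, and adjusted p = 0.0109 with an estimated correlation). Steroid synthesis genes included CYP11A1 (1.89±0.17), the side-chain cleavage enzyme, and CYP19A1 (1.56±0.08), the aromatase. Of 20 genes, 3 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.00328, and adjusted p = 0.0574 with an estimated correlation). HSD11B2, which inactivates cortisol, stood at 0.10±0.10 (adjusted p = 0.738), while its mean over all probe sets was 0.91 (adjusted p = 4.27e-04).

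Markers of trophoblast subtypes moved in both directions in BeWo. Syncytiotrophoblast surface and transport genes were led by the galectin LGALS16 (2.27±0.13) and ENDOU (1.65±0.23). Of 25 genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00328, and adjusted p = 0.0925 with an estimated correlation). Extravillous markers had LAIR2 and MCAM at the top. Of 24 genes, 6 rose and 0 fell (9 and 1 adjusted over the list alone, camera adjusted p = 3.04e-06, and adjusted p = 0.00894 with an estimated correlation). Cytotrophoblast and stem cell markers went down. Of 25 genes, 1 rose and 6 fell (1 and 9 adjusted over the list alone, camera adjusted p = 0.00328, and adjusted p = 0.0654 with an estimated correlation). Its named members were ID1 (-0.88±0.11), TP63 and, upward, ID2 (0.69±0.10, all probe sets 0.34, not called). Metallothioneins, which bind zinc and copper, included MT1F (1.14±0.10) and MT1H (1.10±0.11, all probe sets 0.65). Of 9 genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 1.53e-12, and adjusted p = 0.0351 with an estimated correlation). The arginine transporter SLC7A1 (2.33±0.10) and SLC7A8 (0.75±0.09) led the amino acid transporters and SLC7A11 (-0.41±0.10), the cystine transporter, fell. Of 18 genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.0203, and adjusted p = 0.100 with an estimated correlation). Unfolded protein response genes HERPUD1 (0.97±0.10) and DNAJB9 (0.92±0.15, all probe sets 0.43) rose. Of 20 genes, 3 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.00328, and adjusted p = 0.208 with an estimated correlation). Cytoskeleton genes held LIMA1 (0.51±0.10) and VASP (0.50±0.10). Of 24 genes, 3 rose and 0 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0302, and adjusted p = 0.0925 with an estimated correlation), and the list did not pass over all probe sets (adjusted p = 0.879). Cholesterol synthesis went down, and its only called gene was HMGCS1 (-0.47±0.10). Of 20 genes, 0 rose and 1 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.00328, and adjusted p = 0.121 with an estimated correlation).

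The other lists did not pass the list test in BeWo, apart from 1. Leukocyte and macrophage markers passed it upward, with 1 called gene, the receptor CSF1R (0.80±0.13). Of 16 genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.00556, and adjusted p = 0.227 with an estimated correlation), and the list did not pass over all probe sets (adjusted p = 0.800). Endothelial markers held CDH5 (2.18±0.22), the endothelial cadherin. Of 12 genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.917). Fibroblast markers held FBLN1 (-0.43±0.08). Of 14 genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.485). Dissociation and heat stress genes went both ways, with FOS (0.94±0.13), IER2 (0.56±0.10), JUN (-1.03±0.23, all probe sets -0.68) and BTG2 (-0.45±0.10). Of 19 genes, 2 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.832). Proliferation genes gave no list call. G2/M cell cycle genes held KIF20A (-0.29±0.09, adjusted p = 0.127, all probe sets -0.34, called), and MKI67 stood at 0.14±0.09 (adjusted p = 0.588, all probe sets 0.078). Of 25 genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.178), but the list passed downward over all probe sets (adjusted p = 0.00307). DNA replication held CCNE1 (0.43±0.08) and RRM2 (0.36±0.08, all probe sets 0.26, not called). Of 25 genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.452). Kinase inhibitors held CDKN1A (0.51±0.09, all probe sets 0.17, not called). Of 7 genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.274). Junction genes held OCLN (-0.72±0.13, all probe sets -0.42, not called) and TJP3 (-0.69±0.10, all probe sets -0.36), beside the cadherin CDH1 (-0.31±0.08, adjusted p = 0.0704, all probe sets -0.38, called) and the connexin GJA1 (-0.47±0.20, adjusted p = 0.309, all probe sets 0.16). Of 23 genes, 0 rose and 3 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.199). Apoptosis genes held BCL2L1 (-0.76±0.11). Of 22 genes, 0 rose and 1 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.384). Hypoxia genes held ADM (1.14±0.12). Of 20 genes, 1 rose and 0 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.345). Interferon-stimulated genes held STAT2 (0.64±0.12) and IFIT1 (-1.06±0.17, all probe sets -0.20, not called). Of 19 genes, 1 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.918).

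WNT and TGF-beta genes of BeWo held ID3 (2.18±0.12, all probe sets 1.34), TGFB1 (1.67±0.15) and FZD5 (-0.72±0.11). Of 25 genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.101). Imprinted genes held GRB10 (0.69±0.12), PEG10 (-0.74±0.08) and PEG3 (-0.48±0.09). Of 17 genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.918). Pregnancy-specific glycoproteins (camera adjusted p = 0.854), ribosomal proteins (camera adjusted p = 0.917) and reference genes (camera adjusted p = 0.917) had no called member, over all genes or over the list alone. Their members with the smallest p were PSG7 (-0.33±0.20, adjusted p = 0.523), RPS6 (-0.06±0.07, adjusted p = 0.805, all probe sets -0.10) and B2M (-0.57±0.18, adjusted p = 0.137, all probe sets -0.47, called). The lipid transporter MFSD2A (-0.28±0.25, adjusted p = 0.711, all probe sets 0.048), a receptor of syncytin-2, was not called. Median and mean changes of a list had opposite signs for DNA replication, endothelial, stress and reference genes, and for interferon-stimulated genes the list test pointed up while both were below 0.

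**Figure D1:**
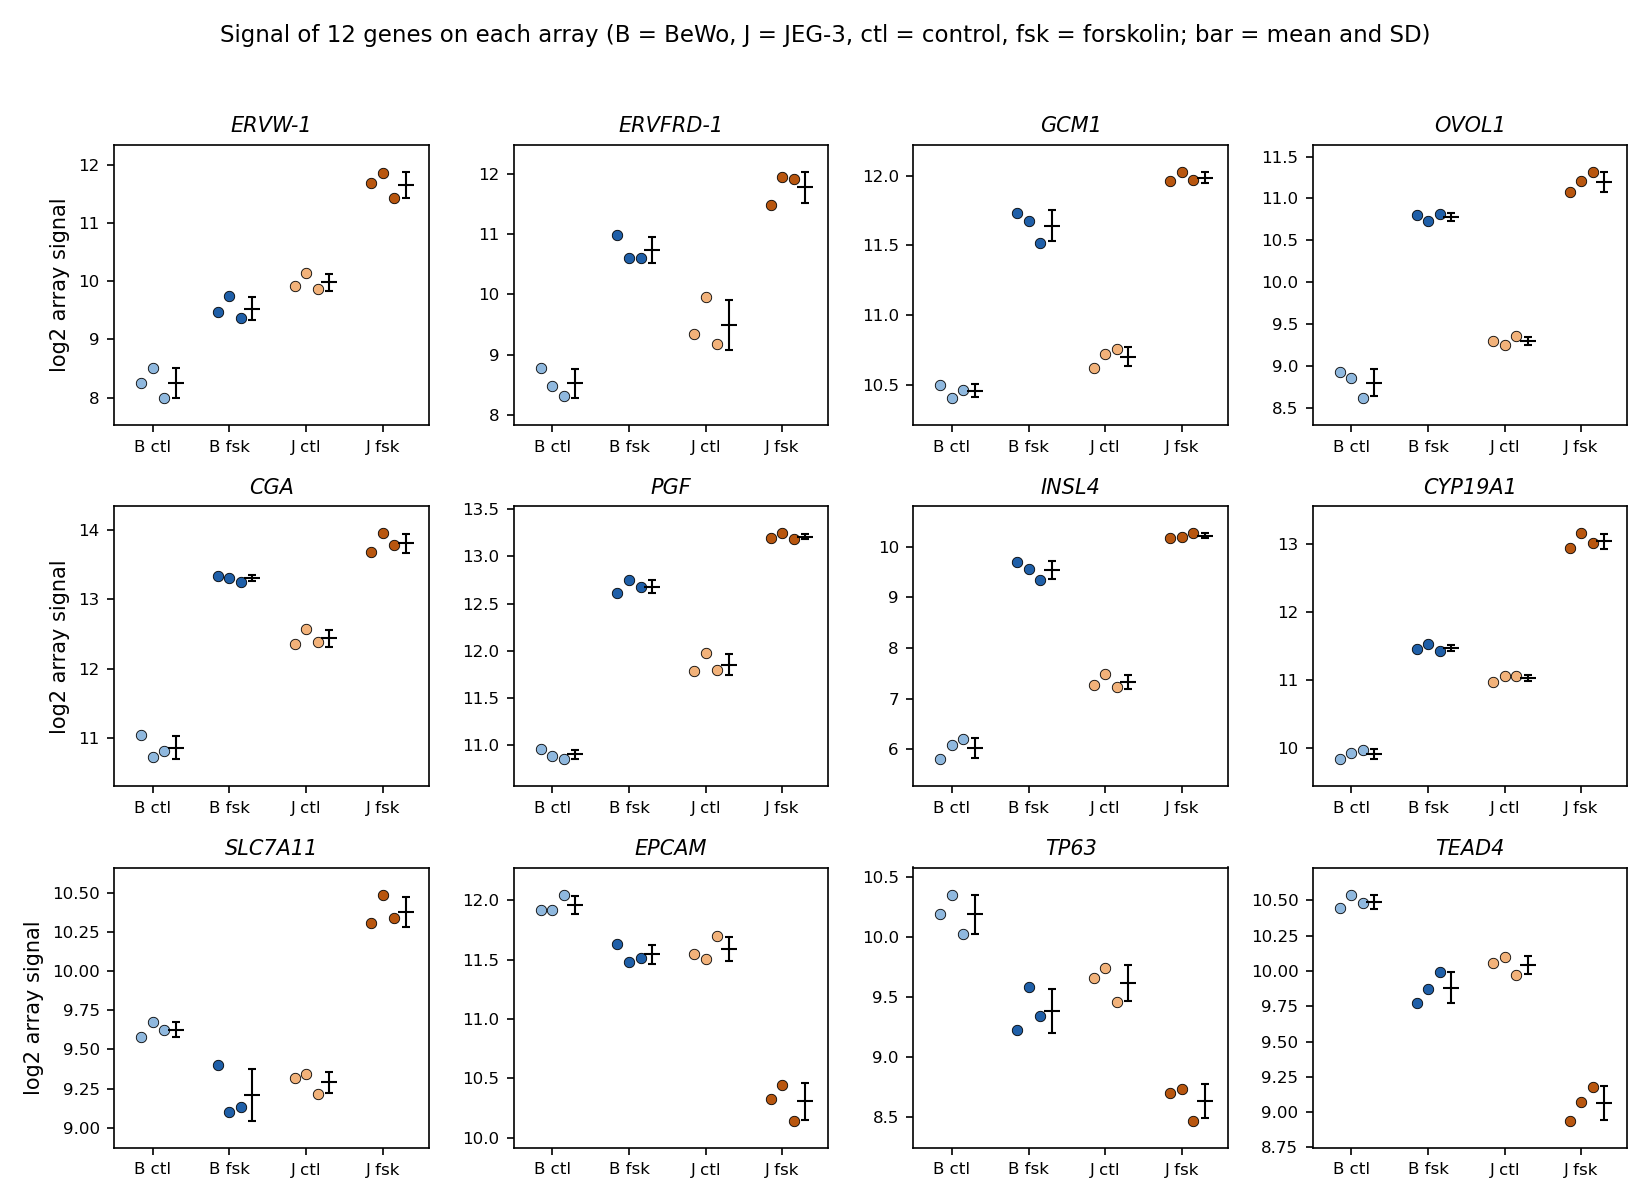
Signal of 12 genes on each of the 12 arrays, as log2 values of the brightest probe set, by group (BeWo control, BeWo forskolin, JEG-3 control, JEG-3 forskolin); points are arrays and bars give the mean and SD of 3 arrays, on a separate axis for each gene. The fusion, hormone and steroid genes in the upper panels lie higher under forskolin in both lines, TP63 and TEAD4 lie lower, SLC7A11 is higher under forskolin in JEG-3 and lower in BeWo, and EPCAM is lowest in forskolin-treated JEG-3.

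In JEG-3 cells INSL4 rose 7.42-fold from 7.32±0.14 to 10.22±0.05 (SD, n = 3 each), a change of 2.89±0.13 (adjusted p = 9.80e-07). Syncytin-2 rose 4.89-fold (2.29±0.22, adjusted p = 7.22e-05), syncytin-1 3.2-fold (1.68±0.16, adjusted p = 8.22e-05) and GCM1 2.44-fold (1.29±0.08, adjusted p = 7.37e-06). Aromatase, CYP19A1, rose from 11.03±0.05 to 13.04±0.11 (2.01±0.08, adjusted p = 9.74e-07). OVOL1 rose by 1.90±0.10 (adjusted p = 4.57e-06), CGA by 1.36±0.11 (adjusted p = 2.73e-05), PGF by 1.36±0.08 (adjusted p = 6.41e-06) and CGB5 by 1.46±0.17 (adjusted p = 2.49e-04). TP63, TEAD4 and CDH1 changed by -0.98±0.13 (adjusted p = 6.09e-04), -0.98±0.09 (adjusted p = 6.79e-05) and -0.34±0.08 (adjusted p = 0.0153).

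In JEG-3, 1880 genes rose and 1581 fell, of which 395 and 236 were at least 2-fold. The largest rises were those of TPPP3 (3.50±0.22, all probe sets 1.82), which promotes tubulin assembly, CRISPLD1 (3.09±0.21), INSL4 (2.89±0.13), TFF1 (2.88±0.17), the glutamine transporter SLC38A3 (2.74±0.24) and LYPD3 (2.65±0.16, all probe sets 1.70). They were followed by the heat shock transcription factor HSF1 (2.60±0.21, all probe sets 0.43), the NF-kappaB inhibitor TNFAIP3 (2.49±0.16), TGFB1 (2.48±0.15, all probe sets 1.55) and the kinase SGK1 (2.46±0.14). The largest falls were those of CASKIN2 (-2.45±0.42, all probe sets -0.36), ENC1 (-2.44±0.10), JAKMIP2 (-2.23±0.35, all probe sets 0.09, not called), LARGE2 (-2.22±0.17, all probe sets -1.14), GCNT2 (-2.21±0.32, all probe sets -1.40) and RUFY4 (-2.11±0.28, all probe sets -0.22, not called). Next came STON1 (-2.09±0.23), SNED1 (-2.09±0.28, all probe sets -0.03, not called), LAMB4 (-2.06±0.54, all probe sets -0.80) and EPHA4 (-1.95±0.21). In HSF1, CASKIN2, JAKMIP2, RUFY4, STON1, SNED1, LAMB4 and GCNT2 the JEG-3 control arrays lay beyond every array of the other groups, though GCNT2 also fell in BeWo. HSF1 stood at 8.54 to 8.77 in the JEG-3 controls and at 10.62 to 11.60 elsewhere. Whether a technical difference of those arrays gave such changes was not tested for single genes. With the mean of all probe sets 1669 genes rose and 1775 fell, but only 1693 genes were called in the same direction by both summaries. The count was 2088 without JEG-3 control replicate 1 and 2280 without JEG-3 control replicate 3.

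Fusion genes of JEG-3 held ERVFRD-1 (2.29±0.22) and SYDE1 (1.90±0.24, all probe sets 1.04). Of 24 genes, 11 rose and 0 fell (14 and 2 adjusted over the list alone, camera adjusted p = 6.53e-06, and adjusted p = 0.0144 with an estimated correlation). Hormone genes were led by INSL4 and ADM (1.78±0.12), with GH2 (-0.88±0.23, all probe sets 0.15, not called) at the other end. Of 22 genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00278, and adjusted p = 0.128 with an estimated correlation). Steroid synthesis held CYP11A1 (2.14±0.17), CYP19A1 and STAR (-0.81±0.13, all probe sets -0.19, not called), the cholesterol carrier of mitochondria. Of 20 genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.0302, and adjusted p = 0.124 with an estimated correlation). HSD11B2 rose by 0.37±0.10 (adjusted p = 0.0237, 1.57 over all probe sets). Cyclic AMP and CREB targets held PDE4B (2.09±0.17, all probe sets 0.28, not called), DUSP1 (1.6±0.12) and RGS2 (-0.86±0.15, all probe sets 0.93). Of 23 genes, 11 rose and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 8.97e-04, and adjusted p = 0.0669 with an estimated correlation). Syncytiotrophoblast genes held ENDOU (2.42±0.23), LGALS16 (2.36±0.13) and XDH (-1.68±0.33, all probe sets -0.02, not called). Of 25 genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 3.89e-04, and adjusted p = 0.0669 with an estimated correlation). Extravillous markers held LAIR2 (2.39±0.14), MCAM (2.18±0.23), NOTCH2 (-0.58±0.10, all probe sets -0.22, not called) and ASCL2 (-0.46±0.11, all probe sets -0.32, not called). Of 24 genes, 11 rose and 3 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.00278, and adjusted p = 0.0669 with an estimated correlation). Metallothioneins held MT2A (1.19±0.12) and MT1F (1.07±0.10). Of 9 genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 2.85e-06, and adjusted p = 0.111 with an estimated correlation).

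Unfolded protein response genes of JEG-3 held DNAJB9 (1.69±0.15), HERPUD1 (1.14±0.10) and CHAC1 (-0.51±0.14, all probe sets -0.07, not called). Of 20 genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 2.53e-05, and adjusted p = 0.103 with an estimated correlation). Amino acid transporters held SLC7A1 (2.41±0.10), SLC7A8 (1.47±0.09) and SLC36A4 (-0.40±0.10, all probe sets 0.09, not called). Of 18 genes, 7 rose and 1 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.00858, and adjusted p = 0.101 with an estimated correlation). Hypoxia genes held ADM and ANKRD37 (1.49±0.20, all probe sets 0.73). Of 20 genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00318, and adjusted p = 0.458 with an estimated correlation). The G2/M cell cycle list went down, with the mitotic genes BUB1B (-0.98±0.13) and CENPF (-0.72±0.12). Of 25 genes, 1 rose and 8 fell (1 and 10 adjusted over the list alone, camera adjusted p = 1.97e-05, and adjusted p = 0.0669 with an estimated correlation). CDK1 was the exception: its brightest probe set rose by 0.38±0.12 and its mean over all probe sets was -0.39 (adjusted p = 0.0174). Imprinted genes went down too, with PEG10 (-1.0±0.08), PEG3 (-0.73±0.09) and, upward, GRB10 (0.86±0.12). Of 17 genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.0197, and adjusted p = 0.228 with an estimated correlation). Over all probe sets it gave adjusted p = 0.192. Cytotrophoblast and stem cell markers did not pass the list test, although over all probe sets they did (adjusted p = 0.0246, downward). Of 25 genes, 3 rose and 9 fell (5 and 10 adjusted over the list alone, camera adjusted p = 0.0731). They held EPCAM (-1.28±0.10), an epithelial adhesion molecule, PEG10, TFAP2A (1.37±0.16) and ID2 (1.21±0.10, all probe sets 0.68). Pregnancy-specific glycoproteins held PSG2 (1.41±0.36) and PSG1 (1.20±0.20, all probe sets 0.45). Of 10 genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0754). Over all probe sets it gave adjusted p = 0.00123, upward.

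Dissociation and heat stress genes of JEG-3 went both ways, with IER3 (1.57±0.19, all probe sets 0.63), FOS (1.40±0.13), SOCS3 (-1.39±0.12, all probe sets -0.04, not called) and ZFP36 (-0.76±0.16, all probe sets -0.10, not called). Of 19 genes, 6 rose and 3 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.191). Over all probe sets it gave adjusted p = 0.0166, upward. Leukocyte markers held CD74 (1.65±0.18, all probe sets 0.92) and CSF1R (1.29±0.13). Of 16 genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.0798). Endothelial markers held CDH5 (2.13±0.22), EGFL7 (0.43±0.09) and CLDN5 (-0.47±0.14, all probe sets -0.26, not called). Of 12 genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.966). Fibroblast markers held LUM (1.05±0.15, all probe sets 0.06, not called). Of 14 genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.616). Cholesterol genes held INSIG1 (0.91±0.12), DHCR7 (0.58±0.09, all probe sets 0.38), TM7SF2 (-0.78±0.22, all probe sets -0.26, not called) and FDPS (-0.32±0.09). Of 20 genes, 2 rose and 2 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.853). DNA replication genes held CCNE1 (0.67±0.08), CDC6 (0.43±0.08) and RFC4 (-0.45±0.09). Of 25 genes, 6 rose and 1 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.315). Kinase inhibitors held CDKN1A (0.66±0.09, all probe sets 0.21, not called) and CDKN1C (-0.52±0.09, all probe sets -0.17, not called). Of 7 genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.979). Junction genes held JUP (0.51±0.10), DSP (0.37±0.09, all probe sets 0.15, not called), OCLN (-0.81±0.13) and CLDN4 (-0.52±0.10, all probe sets -0.20, not called). Of 23 genes, 3 rose and 6 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.415). Cytoskeleton genes held VASP (1.06±0.10), TPM4 (0.61±0.09, all probe sets 0.05, not called), KRT19 (-0.34±0.09, all probe sets -0.56) and TPM1 (-0.30±0.09, all probe sets -0.80). Of 24 genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.236). Apoptosis genes held ATP11A (1.27±0.14), CASP9 (1.26±0.23, all probe sets 0.21, not called), BCL2L1 (-0.86±0.11) and CFLAR (-0.50±0.13). Of 22 genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.808).

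Interferon-stimulated genes of JEG-3 held IRF9 (2.11±0.32, all probe sets 0.36), IFI44 (0.96±0.29, all probe sets 0.11, not called), IFIT1 (-1.43±0.17, all probe sets -0.14, not called) and IFI27 (-0.62±0.19, all probe sets 0.21, not called). Of 19 genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.781). WNT and TGF-beta genes held TGFB1, ID3 (1.61±0.12, all probe sets 0.88), FZD5 (-0.85±0.11) and FZD7 (-0.80±0.10, all probe sets -0.44). Of 25 genes, 6 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.242). Ribosomal proteins held RPL7 (-0.50±0.12, all probe sets -0.22, not called). Of 18 genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.242). Reference genes held TOP1 (0.36±0.08, all probe sets 0.24), HPRT1 (-0.55±0.11) and CYC1 (-0.29±0.09, all probe sets -0.24, not called). Of 13 genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.781). MFSD2A, GJA1 and MKI67 stood at 0.63±0.25 (adjusted p = 0.104, all probe sets 0.064), -0.01±0.20 (adjusted p = 0.987, all probe sets 0.51) and -0.22±0.09 (adjusted p = 0.135, all probe sets -0.066). Median and mean changes had opposite signs for the kinase inhibitor, apoptosis and endothelial lists, none of which passed the list test.

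**Figure D2:**
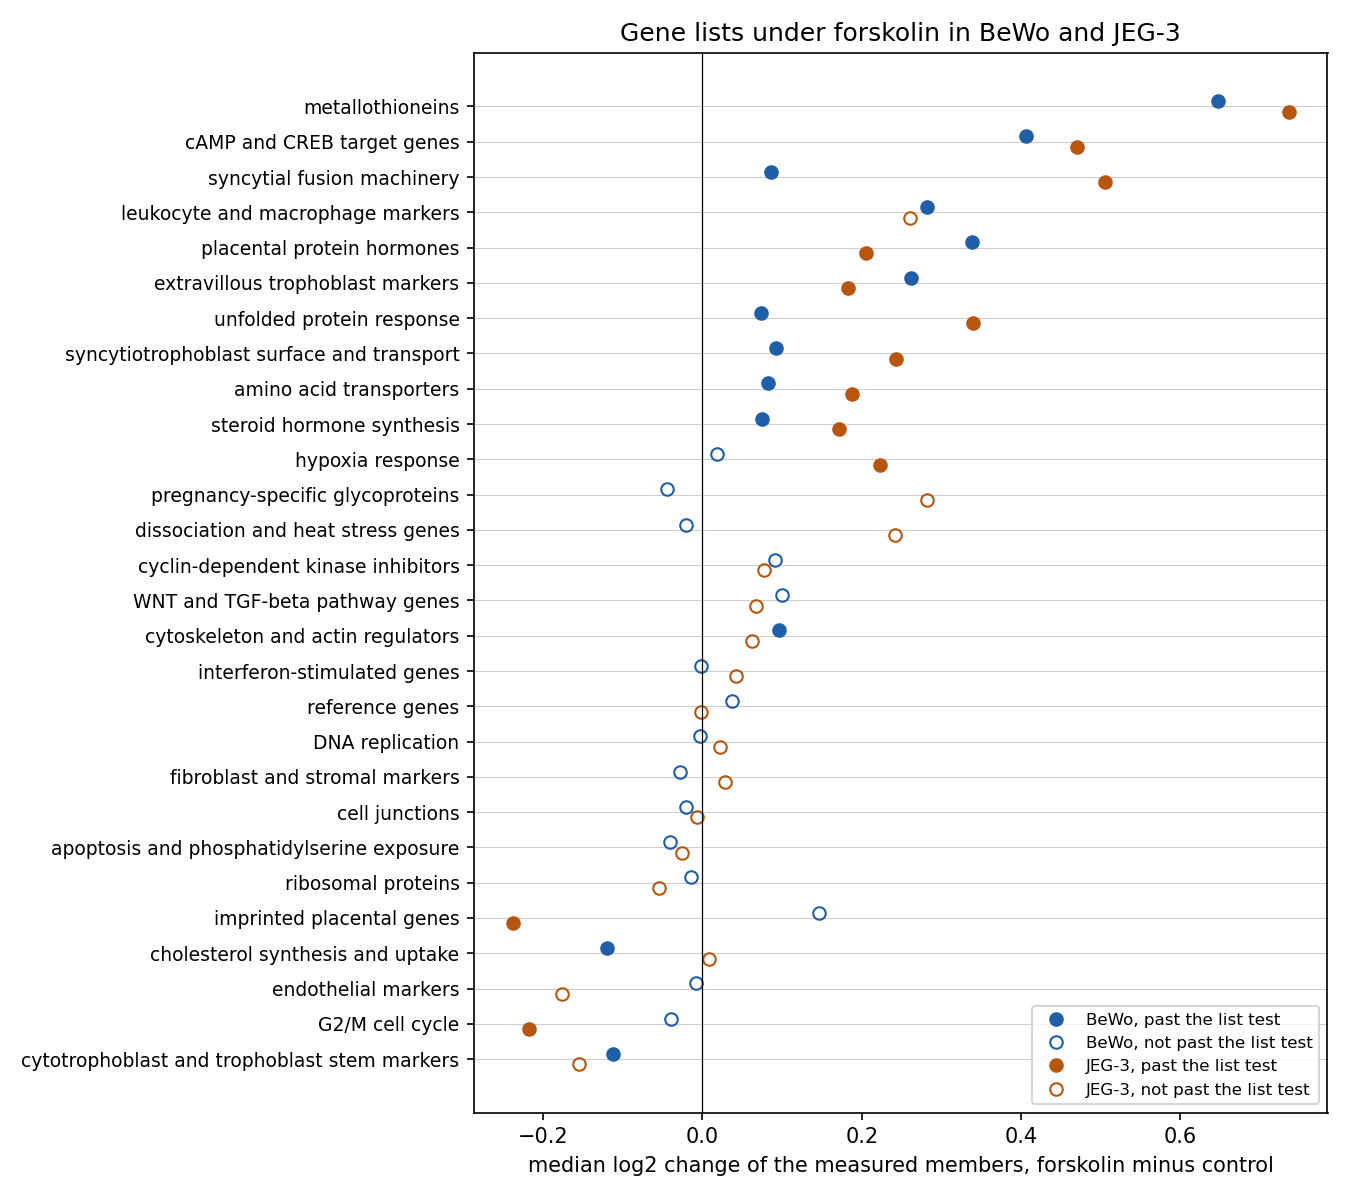
Median log2 change of the measured members of each of 28 gene lists, forskolin minus control, in BeWo (blue) and JEG-3 (orange), from the brightest probe set of each gene. Filled points passed the list test (camera with a preset correlation of 0.01) and open points did not: metallothioneins lie highest in both lines, at 0.65 and 0.74, and 5 of the filled points of BeWo and 1 of JEG-3 kept their call with an estimated correlation.

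The responses of the lines overlapped. Of the genes that rose, 326 were called in both lines against 38.8 expected from independent lists (odds ratio 59.4, Fisher's exact test p = 2.60e-269), and 201 fell in both against 24.7 expected (odds ratio 27.2, p = 3.67e-147). Genes are not independent replicates, so these p-values describe the gene lists only. The lines had separate control arrays, but both tests of a gene used the same estimate of its spread, which the expected counts ignore. The shared genes, 527 in the main fit, were 257 when each line was fitted on its own 6 arrays. They were 275 with the replicate number as a block and 1105 with the mean of all probe sets. Only 9 genes were called in both lines with opposite directions. Across all genes the log2 changes correlated with a Pearson r of 0.390 and a Spearman rho of 0.282, and with the mean of all probe sets these were 0.666 and 0.456. The shared rises included INSL4, TFF1, CRISPLD1, LYPD3, ERVFRD-1, OVOL1, GCM1, CYP11A1 and SLC7A1, and the shared falls ENC1, EPHA4, LARGE2, GCNT2, TP63 and TEAD4.

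**Figure D3:**
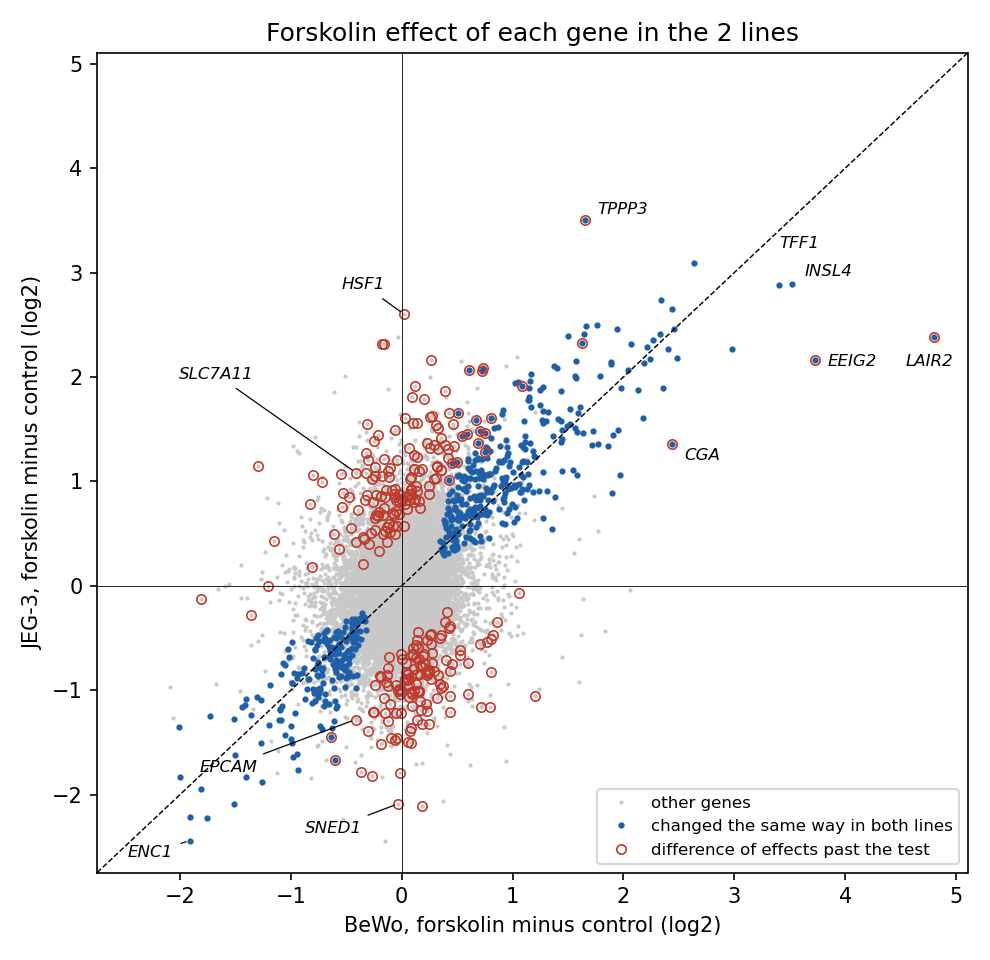
Log2 change of each of 18656 genes under forskolin in BeWo (horizontal axis) and JEG-3 (vertical axis), from the brightest probe set. Blue points are the 527 genes changed in the same direction in both lines, red rings the 282 genes whose difference between the lines passed the test, and the dashed line marks equal changes: LAIR2, EEIG2 and CGA lie on the BeWo side, TPPP3 and SLC7A11 on the JEG-3 side.

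A test of the difference itself, the BeWo effect minus the JEG-3 effect, separated the lines for a small set of genes. The lines were grown in different media, so differences between lines cannot be told apart from those between media. When the replicate number was added as a block, the test called only 1 gene. The cystine transporter SLC7A11 fell in BeWo (-0.41±0.10) and rose in JEG-3 (1.08±0.10), a difference of -1.5±0.14 (adjusted p = 0.00236). EEIG2 rose more in BeWo (1.57±0.19, all probe sets 1.02). CGA also had a higher effect in BeWo (1.08±0.16, adjusted p = 0.0181), but its signal in treated JEG-3 (13.80±0.14) lay near the array maxima of 14.11 to 14.22, which limits how far a rise can be read there. Larger effects in JEG-3 were measured for TPPP3 (-1.85±0.31, all probe sets -0.99), SLC7A8 (-0.72±0.13), the progesterone-forming enzyme HSD3B1 (-0.76±0.12), the protease ADAM19 (-1.06±0.14) and CD74 (-1.22±0.25). EPCAM fell in JEG-3 (-1.28±0.10). In BeWo it gave -0.42±0.10, not called, and -0.43 over all probe sets, called (adjusted p = 0.00251), with a difference of 0.86±0.14 (adjusted p = 0.0233). These genes were called by both gene summaries, which are not independent, since the mean of all probe sets includes the brightest. LAIR2 had the largest positive difference (2.42±0.19, adjusted p = 0.00115), which was 0.56 over all probe sets and -0.37, not called, with its brightest probe set left out.

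In all, 129 genes had a higher (more positive) and 153 a lower effect in BeWo than in JEG-3. Of these 282 genes, 240 were called in JEG-3 alone, 9 in BeWo alone, 32 in both and 1 in neither. The estimated changes of 167 had opposite signs in the lines, whether or not the gene was called in each. Over all genes, only 9 were called in both lines with opposite directions. After LAIR2, the largest positive differences were those of RUFY4 (2.29±0.40, all probe sets 0.28, not called), CCDC112 (2.26±0.11, all probe sets 0.28, not called), SNED1 (2.06±0.40, all probe sets -0.02, not called), OSBP2 (1.95±0.35, all probe sets 0.26, not called) and CHD5 (1.88±0.30, all probe sets 0.45, not called). Next came FSD1L (1.77±0.37, all probe sets -0.02, not called), CAMK4 (1.65±0.25, all probe sets -0.14, not called), NLRC5 (1.64±0.28, all probe sets 0.02, not called) and PTGR1 (1.63±0.32, all probe sets 0.15, not called). The largest negative differences, TPPP3 aside, were those of HSF1 (-2.58±0.29, all probe sets -0.36, not called), KATNAL1 (-2.50±0.45, all probe sets -0.46, not called), UNKL (-2.47±0.27, all probe sets 0.04, not called) and MGAT4C (-2.44±0.51, all probe sets 0.14, not called). They were followed by ARHGAP44 (-1.90±0.22, all probe sets 0.17, not called), RPAP2 (-1.87±0.34, all probe sets -0.05, not called), PRDM9 (-1.86±0.34, all probe sets -0.51, not called), RESP18 (-1.79±0.22, all probe sets -0.17, not called) and GSTM2 (-1.72±0.36, all probe sets -0.31, not called). In each gene listed here from RUFY4 to GSTM2, other than TPPP3 and MGAT4C, the JEG-3 control arrays lay beyond every array of the other groups. Other called list members were DHCR7 (-0.65±0.13, all probe sets -0.45, not called), PDE4B (-1.35±0.24, all probe sets -0.22, not called), TFAP2A (-1.13±0.22, all probe sets -0.53, not called), FZD7 (0.91±0.15, all probe sets 0.08, not called), LUM (-1.22±0.21, all probe sets -0.40, not called), SOCS3 (1.08±0.16, all probe sets 0.47, not called) and MEST (0.73±0.16, all probe sets 0.26, not called). With the mean of all probe sets 39 genes had a higher and 116 a lower effect in BeWo, and only 40 genes were called in the same direction by both summaries. Of the 282 genes, 65.2% had other probe sets moving the same way, and 56.3% of those at 2-fold or more. The count was 1 with the replicate number as a block, and 1 with each probe set tested singly. It fell to 26 without JEG-3 control replicate 1, 43 without JEG-3 control replicate 3 and 48 without JEG-3 forskolin replicate 2. Without 6 other single arrays it also fell by over 1.5 times.

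Among the gene lists, G2/M cell cycle genes fell less in BeWo than in JEG-3 (median change -0.04 against -0.22). In BeWo the list did not pass from the brightest probe set, but passed downward over all probe sets (camera adjusted p = 0.00307). Its median difference was 0.21 (camera adjusted p = 7.52e-04, and adjusted p = 0.375 with an estimated correlation). Of 25 genes, 0 were called and 2 were higher in BeWo adjusted over the list alone. The smallest p was that of BUB1B (0.81±0.19, adjusted p = 0.0642, all probe sets 0.38). The difference of imprinted genes was positive too (0.26, camera adjusted p = 0.0175, and adjusted p = 0.375 with an estimated correlation, and adjusted p = 0.244 over all probe sets). The remaining 3 called lists had lower effects in BeWo: the unfolded protein response (-0.25, camera adjusted p = 0.00673, and adjusted p = 0.375 with an estimated correlation), hypoxia genes and cholesterol genes. Hypoxia genes gave -0.26 (camera adjusted p = 0.0175, and adjusted p = 0.614 with an estimated correlation). Cholesterol genes gave -0.20 (camera adjusted p = 0.0342, and adjusted p = 0.375 with an estimated correlation, and adjusted p = 0.476 over all probe sets). Over the list alone, 1 unfolded protein response gene had a higher and 9 a lower effect in BeWo, and 0 hypoxia genes and 3 cholesterol genes had a lower one. The other 23 lists did not pass, among them pregnancy-specific glycoproteins (camera adjusted p = 0.0634) and syncytiotrophoblast genes (camera adjusted p = 0.0776), which passed downward over all probe sets (adjusted p = 0.00208 and adjusted p = 0.0130). Steroid synthesis and dissociation and heat stress genes passed downward and ribosomal proteins upward over all probe sets (adjusted p = 0.0463 for each). For the fusion list 0 of 24 genes differed (camera adjusted p = 0.173, and adjusted p = 0.0463 over all probe sets), and the differences of ERVFRD-1, ERVW-1, GCM1 and OVOL1 were -0.08±0.31 (adjusted p = 0.929), -0.41±0.23 (adjusted p = 0.407, all probe sets -0.70), -0.10±0.12 (adjusted p = 0.718, all probe sets 0.13) and 0.08±0.14 (adjusted p = 0.819, all probe sets -0.18).

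Without forskolin, BeWo and JEG-3 differed in 3908 genes, 2149 higher in BeWo and 1759 higher in JEG-3. THSD7A, a thrombospondin-domain protein, was higher in BeWo by 3.71±0.16 (adjusted p = 1.76e-06), and the bicarbonate transporter SLC4A8 by 2.46±0.12 (adjusted p = 1.92e-06). JEG-3 had more of LAIR2 (-3.48±0.14, all probe sets -1.45), the phospholipid transfer protein PLTP (-3.01±0.21, adjusted p = 4.38e-05), the interferon-induced IFITM3 (-2.96±0.22, adjusted p = 5.06e-05), the kinase inhibitor CDKN2A (-2.95±0.31, all probe sets -1.26) and the proteasome subunit PSMB8 (-2.77±0.29, all probe sets -0.64). The remaining large differences were those of C22orf23 (3.93±0.64, all probe sets 0.23, not called), HSF1 (2.50±0.21, all probe sets 0.19, not called) and CAPN9 (2.47±0.24, all probe sets -0.08, not called). The lines were grown in different media, so line and medium cannot be told apart. With the mean of all probe sets 1177 genes were higher in BeWo and 1106 in JEG-3, 1105 of them called in the same direction by both summaries. The other probe sets moved the same way for 70.5% of the called genes, and for 63.4% of those at 2-fold or more. The count was 2116 without JEG-3 control replicate 1, 2420 without JEG-3 control replicate 3 and 2274 without BeWo control replicate 2.

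Among treated cells, SLC7A11 stood lower in BeWo than in JEG-3 and EPCAM higher, with BeWo minus JEG-3 differences of -1.17±0.10 (adjusted p = 1.11e-04) and 1.24±0.10 (adjusted p = 8.32e-05). Both were chosen after their values were seen. Of the genes fixed by name, CGA, CYP19A1 and INSL4 gave -0.50±0.11 (adjusted p = 0.0200, all probe sets -0.79), -1.57±0.08 (adjusted p = 8.54e-06) and -0.68±0.13 (adjusted p = 0.00929). Under forskolin the lines differed in 1491 genes, 829 higher in BeWo and 662 higher in JEG-3, of which 58 and 140 by at least 2-fold. With the mean of all probe sets 1628 and 1386 genes differed. As in the controls, line and medium cannot be told apart here. The count was 829 without JEG-3 forskolin replicate 2, 902 without BeWo forskolin replicate 1 and 396 in a fit of the 6 treated arrays alone.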

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

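Most tests of explanations here had their predictions written before the result each one measures, but the bounds from leaving out arrays, the test of mixing against 50%, the reverse selection of genes, the support by size and by comparison, the grouping of the splits by JEG-3 labels and the splits of residuals were chosen after the results were seen.

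A difference between the lines in the forskolin effect drew attention to the following genes and to 5 gene lists. Called by both gene summaries were LAIR2 2.42, EEIG2 1.57, CGA 1.08, TPPP3 -1.85, SLC7A8 -0.72, SLC7A11 -1.5, EPCAM 0.86, CD74 -1.22, HSD3B1 -0.76 and ADAM19 -1.06 (BeWo effect minus JEG-3 effect, log2). Of these, LAIR2 turned to -0.37 with its brightest probe set left out, and CGA lay near the top of the array signal in treated JEG-3. Called from the brightest probe set only were SLC44A5 -1.69, HSF1 -2.58, RUFY4 2.29, SNED1 2.06, CCDC112 2.26, OSBP2 1.95, CHD5 1.88, FSD1L 1.77, CAMK4 1.65, NLRC5 1.64, PTGR1 1.63, KATNAL1 -2.50, UNKL -2.47, MGAT4C -2.44, ARHGAP44 -1.90, RPAP2 -1.87, PRDM9 -1.86, RESP18 -1.79, GSTM2 -1.72, DHCR7 -0.65, PDE4B -1.35, TFAP2A -1.13, FZD7 0.91, LUM -1.22, SOCS3 1.08 and MEST 0.73. The lists were cholesterol synthesis (median difference -0.20), G2/M cell cycle (0.21), unfolded protein response (-0.25), hypoxia (-0.26) and imprinted genes (0.26). Of 100 splits of the arrays within lines, 9 gave as many genes as the real 282, and the highest other gave 1328. The 8 besides the real one kept the JEG-3 labels and so counted the JEG-3 response as a difference, and these splits therefore do not decide whether chance can be excluded. In a second test the line and treatment effects were taken out and the residuals dealt anew to the arrays. Of 100 such splits of the residuals once line and treatment effects are taken out, 1, the real one, gave as many as 282 genes and the highest other gave 1, and of 100 splits within each replicate number of the residuals 1, the real one, did and the highest other gave 5. Chance can therefore be excluded for the count only if the arrays are independent samples, which the sources do not state. A technical cause, such as a structure common to the forskolin arrays of both lines, is not excluded. The count itself depended on the model: it was 1 with the replicate number as a block, and 1 with each probe set tested singly. For the lists chance cannot be excluded. As many as the real 5 came from 4 of the 100 splits of all residuals (highest other 6), from 9 of the 100 splits within replicate numbers (highest other 6) and from 15 of the splits within lines (highest other 11), 8 of which kept the JEG-3 labels and 6 did not, and with an estimated correlation 0 lists differed.

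Signal in probe sets that the gene tests do not use came from 20 probe sets annotated to several CGB genes, the beta subunits of chorionic gonadotropin. Their median change was 2.81 in BeWo, where 15 rose and 0 fell, and 2.72 in JEG-3, where 17 rose and 0 fell. The median level went from 6.67 to 9.23 in BeWo and from 8.51 to 11.47 in JEG-3. For 0 of the 20 was the difference in effect between the lines called, although the differences ran from -1.92 to 1.94. The singly annotated CGB5 and CGB7 gave -0.96 (adjusted p = 0.0779) and -0.91 (adjusted p = 0.0615, and 0.0446 over all probe sets). Probe sets shared by similar genes cannot tell which CGB gene changed.

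JEG-3 had 3461 called genes and BeWo 677. The share of called genes whose other probe sets moved the same way was 14.3 percentage points lower in JEG-3 than in BeWo (78.9% against 93.2%), and it was low in the other comparisons that use the JEG-3 controls (70.5% between control lines, 65.2% for the difference) and high between treated lines (95.2%), as single displaced probe sets in the JEG-3 controls would give. Among probe sets numbered below the lowest annotated one, the called share in JEG-3 was 6.93 times that in BeWo (2.31% against 0.333%), but among the other probe sets it was higher too (6.44% against 1.47%). Among the low-numbered probe sets it was 3.97% between control lines and 1.59% between treated lines. The latter comparison uses no JEG-3 control, so those controls are not the only source of such calls. With each gene as the mean of its other probe sets, JEG-3 still had 2.46 times the calls of BeWo (3116 against 1268). That mean leaves out only the brightest probe set and may hold other displaced ones. It therefore cannot decide whether displaced probe sets make up the whole excess. A technical difference of the JEG-3 control arrays may therefore add to the counts that use them, and a stronger response of JEG-3 stays open and was not tested apart from it.

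The responses of the lines ran in parallel, with 527 shared genes. Over the 2283 genes called between the controls, the line difference kept 77.0% of its size in the forskolin arrays, and at least 74.5% (at most 79.1%) with single forskolin arrays left out. Every value lies above the 50% that would be left if treated arrays of a line held enough cells of the other to take away 50% of the difference, and genes picked in the controls tend to shrink on a second measurement, so such mixing is argued against. A smaller share of other cells cannot be told apart from that shrinkage, since the bound of 75% written before lies within the range, and mixing alike in control and treated arrays would not change this measure. Requiring the whole range above 75% was added after 77.0% was seen, and over genes called between the treated lines the reverse measure was 58.5%.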

How the results depend on the processing

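The median of all probe sets, the mean with the brightest left out, the residual component and the lists over the mean or median of probe sets were chosen after seeing the data. The cause was not tested for any change below, except that a 2-fold minimum on top of the adjusted p lowers a count by construction. Counts moved by over 1.5 times, and correlations moved beyond their spread between arrays, were, with the mean of all probe sets, 1366 for BeWo, 155 for the difference, 2283 for the control lines, 3014 for the forskolin lines, 1105 for the shared response, 0.666 for the correlation of effects and 9 for difference lists. With the median they were 30 for the difference, 1326 for the control lines, 0.543 for the correlation of effects and 8 for difference lists, and with the brightest left out 1268 for BeWo, 125 for the difference, 1883 for the control lines, 2682 for the forskolin lines, 1016 for the shared response and 0.669 for the correlation of effects. Each probe set tested singly gave 3732 for BeWo, 16314 for JEG-3, 1 for the difference, 10795 for the control lines and 7035 for the forskolin lines. A 2-fold minimum gave 178 for BeWo, 631 for JEG-3, 145 for the difference, 640 for the control lines, 198 for the forskolin lines and 126 for the shared response, and an unadjusted p with a 2-fold minimum 216 for BeWo, 687 for JEG-3, 550 for the difference, 702 for the control lines, 236 for the forskolin lines and 131 for the shared response. The 6 arrays compared alone gave 304 for BeWo, 396 for the forskolin lines and 257 for the shared response. Dim genes removed gave 661 for the difference, 0.555 for the correlation of effects and 3 for difference lists. The trended and robust prior gave 589 for the difference, array weights 519 for the difference, and the residual component 568 for the difference. An estimated correlation gave 5 for BeWo lists, 1 for JEG-3 lists and 0 for difference lists, and fry 21 for JEG-3 lists and 9 for difference lists. Quantile normalization and median centring moved no count by over 1.5 times. With single arrays left out the values ran from 450 to 674 for BeWo, 2088 to 3679 for JEG-3, 26 to 295 for the difference, 2116 to 4133 for the control lines, 829 to 1351 for the forskolin lines, 385 to 504 for the shared response, 0.335 to 0.391 for the correlation of effects, 10 to 13 for BeWo lists, 11 to 13 for JEG-3 lists and 2 to 6 for difference lists.

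Same-numbered control and forskolin arrays of a line are not paired by their values: their deviations correlated by -0.20, -0.08 and -0.024 in BeWo and 0.0041, 0.07 and 0.012 in JEG-3, and 2 of 6 matched their own number best. Between lines, in a check added after the results were seen, they correlated by 0.06, 0.08 and 0.033 for controls (2 of 3 matched their own number best) and by 0.13, -0.05 and 0.18 for forskolin arrays (1 of 3), so not all passed 0.1. The residual component nevertheless fell with the number in the forskolin arrays of both lines (0.24, 0.16 and -0.40 in JEG-3, 0.54, -0.026 and -0.51 in BeWo), so a structure common to them is not excluded. With the number as a block the values were 319 for BeWo, 2197 for JEG-3, 1 for the difference and 275 for the shared response.

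Some named genes changed direction with the gene summary. With the mean of all probe sets these were in JEG-3 JAKMIP2 0.085, GH2 0.15, RGS2 0.93, CDK1 -0.39, IFI27 0.21 and SLC36A4 0.089, for the difference SNED1 -0.021, FSD1L -0.024, CAMK4 -0.14, UNKL 0.038, MGAT4C 0.14 and ARHGAP44 0.17, and between control lines CAPN9 -0.082. With the median they were in BeWo ID2 -0.032, in JEG-3 JAKMIP2 0.035, SNED1 0.19, GJA1 1.17, GH2 0.35, RGS2 1.13, CDK1 -0.38, IFI44 -0.082, IFIT1 0.13, IFI27 0.78, SLC36A4 0.35, LUM -0.17 and SOCS3 0.45, for the difference FSD1L -0.046, CAMK4 -0.49, NLRC5 -0.19, UNKL 0.11, MGAT4C 0.28, RPAP2 0.36, RESP18 0.26, FZD7 -0.28 and SOCS3 -0.13, and between control lines C22orf23 -0.076, HSF1 -0.020 and CAPN9 -0.15. With the brightest left out they were in BeWo IFIT1 0.088, in JEG-3 JAKMIP2 0.18, SNED1 0.043, GH2 0.32, RGS2 1.10, CDK1 -0.46, XDH 0.029, TPM4 -0.057, CHAC1 0.0053, IFIT1 0.29, IFI27 0.35, SLC36A4 0.13, LUM -0.14, SOCS3 0.30 and ZFP36 0.23, for the difference LAIR2 -0.37, SNED1 -0.091, FSD1L -0.15, CAMK4 -0.29, NLRC5 -0.0087, UNKL 0.14, MGAT4C 0.38, ARHGAP44 0.26, RPAP2 0.084, RESP18 0.056, MT2A 0.68 and FZD7 -0.20, and between control lines C22orf23 -0.18 and CAPN9 -0.20. Among lists, the signed -log10 p was, with the median, cytoskeleton and actin regulators (BeWo forskolin effect) -0.064, leukocyte and macrophage markers (BeWo forskolin effect) -0.048, endothelial markers (JEG-3 forskolin effect) 1.92 and extravillous trophoblast markers (difference of effects) -2.04, and with dim genes removed imprinted placental genes (BeWo forskolin effect) -1.73. Of 220 called gene results, 156 kept direction and call with the mean of all probe sets, 51 lost the call and 13 turned. The median kept 129, lost 67 and turned 24 of the 220. Leaving the brightest out kept 137, lost 49 and turned 28 of 214. The replicate number as a block kept 149 and lost 71 of 220, and fits on the 6 arrays compared kept 160 and lost 26 of 186. Without detection calls, signal over background limits what dim probe sets can show.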

Other observations

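Genes with at least 4 probe sets were also ranked by the mean of all probe sets, a choice made after the results were seen. Of the 25 that rose most in both lines, 19 were called as rises in both from the brightest probe set too, and of the 25 that fell most 17 were called as falls in both. Values are BeWo and JEG-3 log2 changes. Among those in agreement were MCAM (2.20 and 2.20, brightest probe set 2.49 and 2.18), the receptor kinase GRK5 (1.96 and 2.02, brightest probe set 2.04 and 2.06) and the myosin MYO10 (1.65 and 1.62, brightest probe set 1.63 and 1.47) upward, and the annexin ANXA6 (-1.30 and -1.48, brightest probe set -0.93 and -0.85) and the fibrillin FBN2 (-1.29 and -1.36, brightest probe set -1.44 and -1.16) downward. The 6 other rises were WIPF1 (3.07 and 2.77, brightest probe set 1.07 and 0.40), which binds the actin regulator WASP, the serine protease HTRA4 (2.31 and 2.64, brightest probe set 0.26 and 0.17), the transglutaminase TGM2 (2.23 and 2.19, brightest probe set 0.16 and -0.43), the nuclear receptor NR4A3 (2.67 and 2.05, brightest probe set 0.48 and -0.23), CRIP2 (1.97 and 2.70, brightest probe set 0.0081 and -0.065) and the calcium-binding CALB2 (2.05 and 1.75, brightest probe set 0.0097 and 0.18). From the brightest probe set WIPF1 was called in BeWo alone, TGM2 was called as a fall in JEG-3 (adjusted p = 0.0459), and the other 4 were called in neither line. The 8 other falls were the lysyl oxidase LOXL2 (-1.10 and -1.08, brightest probe set -0.34 and -0.93), the WNT ligand WNT11 (-1.04 and -0.94, brightest probe set -0.11 and -0.28), the proteases TMPRSS2 (-0.97 and -1.01, brightest probe set -0.32 and -0.19) and PRSS12 (-1.23 and -1.19, brightest probe set -0.21 and -0.27), NRP2 (-0.91 and -1.08, brightest probe set -0.035 and -0.36), DDAH1 (-1.0 and -1.15, brightest probe set 0.045 and -0.20), TMEM131L (-1.35 and -1.04, brightest probe set -0.034 and 0.38) and the sodium chloride transporter SLC12A3 (-1.28 and -1.05, brightest probe set -0.64 and 0.36). From the brightest probe set LOXL2 was called in JEG-3 alone and the other 7 in neither line.

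Differences by the same summary, BeWo effect minus JEG-3 effect, were negative for PLAC4 (-1.40, adjusted p = 0.00415, from 0.49 in BeWo and 1.90 in JEG-3), the Notch ligand JAG1 (-1.30, adjusted p = 0.00276, from -0.22 in BeWo and 1.08 in JEG-3), the aryl hydrocarbon receptor AHR (-1.23, adjusted p = 0.00809, from 0.28 in BeWo and 1.51 in JEG-3) and the protease BACE2 (-1.31, adjusted p = 0.00415, from -0.024 in BeWo and 1.28 in JEG-3). They were positive for the fatty acid binding protein FABP7 (0.96, adjusted p = 0.00331, from 1.0 in BeWo and 0.045 in JEG-3) and the kinase DAPK1 (0.84, adjusted p = 0.00484, from 0.40 in BeWo and -0.45 in JEG-3). From the brightest probe set the difference was called for FABP7 1.13 (adjusted p = 0.0169) and not for DAPK1 0.69 (adjusted p = 0.0689), PLAC4 -0.67 (adjusted p = 0.323), JAG1 -0.95 (adjusted p = 0.182), AHR -0.24 (adjusted p = 0.840) and BACE2 0.031 (adjusted p = 0.967).

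A hypothesis noticed in the data, with its bounds written before its test, was that genes raised by forskolin in JEG-3 are already higher in untreated JEG-3 than in untreated BeWo. With the mean of all probe sets, 1669 genes rose in JEG-3. Their median difference, BeWo control minus JEG-3 control, was -0.036, between the bounds of -0.1 and 0 fixed for it. Of these genes 55.0% were higher in JEG-3, against 48.9% of all genes and 49.6% of those that fell in JEG-3. Of 10000 random gene lists of that size and of like signal, the middle 95% gave -3.92e-06 to 0.022. The JEG-3 controls enter both the rise and the difference, which biases the median upward. The test leaves the hypothesis open.

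Splits of the arrays within lines gave no other shared response as large as the real 527 genes. Of 100 splits 1, the real one, reached it and the highest other gave 0. Wrong splits of a single line called at most 1 gene in BeWo and 0 in JEG-3, which left almost nothing to share. These splits therefore test only whether both lines respond, and cannot decide whether the overlap exceeds chance. For comparisons of 3 arrays against 3, the 10 splits are too few for a share under 0.05. In each of these, 1 of the 10 splits, the real one, gave a result as large. The real count and the highest other were 677 and 1 in BeWo, 3461 and 0 in JEG-3, 3908 and 0 for the control lines, 1491 and 0 for the treated lines, 13 and 3 for BeWo lists, and 12 and 3 for JEG-3 lists.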
